A study of Arabidopsis thaliana with 6 samples.

How the data were processed

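Closed flower buds of Arabidopsis thaliana, either wild type or carrying naa50-1, were sequenced as RNA in 3 biological replicates per genotype, per the labels and the series design. The reads were aligned with HISAT2 2.0.5 to TAIR10, per the submitters' processing notes. The read counter, the annotation release and the strand setting are not given in the sources used here. Whole-number read counts per gene were deposited by the authors for 33037 features, of which 204 carry no annotated gene. FPKM values were also deposited by the authors; in each library they equalled the counts divided by gene length and by a median-of-ratios size factor times a constant shared by all libraries. The authors' deposited comparison table holds a log2 fold change, a p-value and an adjusted p per gene. It also holds the authors' normalized signal per group, which equals the group mean of the deposited counts divided by median-of-ratios size factors. Gene coordinates in the deposited files equalled the TAIR10.1 reference exon bounds for 99.5% of 32548 matched genes.

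Groups and replicate numbers were taken from the sample labels. Library totals ranged from 19727584 to 20813563 counts. Replicates of a group differed by far more than sampling noise (chi-square per degree of freedom 12.9 to 28.2), so none was a duplicate. Counts were scaled by TMM and filtered by filterByExpr, and the genotypes were compared with the edgeR 4.0.16 quasi-likelihood test with genotype alone as covariate (R 4.3.3), with Benjamini-Hochberg adjustment and a threshold of 0.05. Group values are mean CPM ± SD over 3 libraries. A fold against a group with 0 counts was taken against a floor of 3 counts over the group. These bounds and the intervals of ratios cover counting error only.

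A total of 17 gene lists and 14 gene families matched by words of their descriptions were fixed before the data were examined; 13 families had at least 10 tested members. The entries CEP2 and CEP3 were dropped from the cell death list because the file exchanges their names. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with an estimated correlation, and with fry. By the preset camera 9 of 17 lists passed, by the estimated correlation 0, and by fry 5. The preset and fry counts include the acetylation complex list, which holds NAA50 itself. Named genes were chosen by a rule fixed beforehand: NAA50; the 7 largest rises and 7 largest falls by fitted log2 fold change among genes past the threshold with a mean of at least 50 counts in the higher group and no overlap between groups; and from each list the members with the smallest p past the threshold, up to 4 for the 5 pollen, tapetum and cell death lists and up to 2 for the others, all of them where 3 or fewer passed, and the smallest p where none did. Non-overlapping groups were found in 5278 tested genes (24.9%; chance gives 10%).

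Exonic sequences of the named genes were compared with all reference transcripts by blastn 2.17.0. At 95% identity over 100 bases, 7 of 46 genes had a match and 12 overlapped another gene. Because no strand setting is given, reads of overlapping genes on opposite strands may not be separated.

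The test was run on simulated counts with known changes. These were given to 67, 67 and 66 genes at 1.5-, 2- and 4-fold, none with low wild-type counts. Far fewer genes were changed than are called in the data, so the rates need not hold there. Among 20827 genes, edgeR recovered 17.9% of genes changed by 1.5-fold, 68.7% of those changed by 2-fold and 90.9% of those changed by 4-fold, and 16 of 134 calls were false. Alternatives were other scalings, other filters, DESeq2 1.42.0, limma-voom, limma on log2(FPKM + 1) and log2(FPKM + 0.1), other thresholds, the replicate number as a block, and each library left out in turn.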

Results

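Messenger RNA abundance was measured by RNA sequencing in closed flower buds of Arabidopsis thaliana, in 3 biological replicates of the wild type and 3 of the naa50-1 mutant. NAA50 encodes a catalytic subunit that acetylates the amino termini of proteins, and the title of the series places its role in the breakdown of the tapetum, the inner anther layer that feeds developing pollen. The libraries held between 19727584 and 20813563 counts each. On log2 CPM (counts scaled by library size), libraries of 1 genotype label correlated across genes at 0.977 to 0.986, and libraries of different labels at 0.876 to 0.914. The first principal component held 80.4% of the variance and separated the labels. On the second component (6.38%) wild type replicate 2 stood apart, at -38.1 against 20.7 for each of the other wild-type libraries. It also had the highest shares of mitochondrial counts (0.0283%) and of counts in the mature pollen list (0.253%).

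The targeted gene was examined first, as a check of the labels. NAA50 (AT5G11340, TAIR10 chromosome 5, 3619152 to 3621511, plus strand, 3 exons) was higher, not lower, in the libraries labelled naa50-1. It stood at 26.3 ± 2.39 CPM in the wild type and at 2680 ± 295 CPM in the libraries labelled naa50-1 (SD, n = 3 each), a 102-fold rise with a log2 fold change of 6.67 (SE 0.19, adjusted p = 6.5e-08, edgeR quasi-likelihood test). The deposited FPKM values gave 25.9 ± 2.35 and 2641 ± 291. This direction goes against what a loss of the transcript would give, and the labels do not say where the naa50-1 allele lies in the gene. All directions below are therefore those of the libraries labelled naa50-1. The next gene downstream on the same strand, AT5G11350 (3621454 to 3625645), shares 58 bases with NAA50, and reads over those bases cannot be assigned to either gene with certainty. It rose from 27.4 ± 1.56 to 959 ± 151 CPM (log2 fold change 5.13, adjusted p = 1.58e-07, edgeR). Among the 5 tested genes on each side of NAA50, it alone passed the threshold. AT5G11330, directly upstream, had a log2 fold change of -0.07, and AT5G11360, which overlaps the end of AT5G11350 on the other strand, had -0.51.

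**Figure D1:**
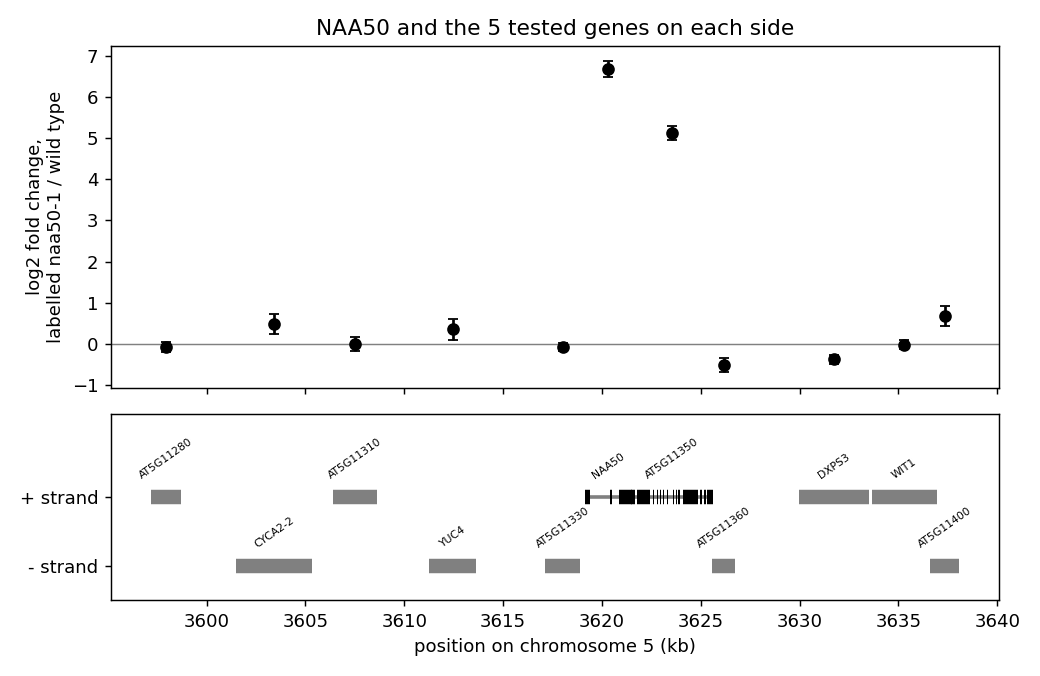
Log2 fold change (upper panel, points, with bars of 1 SE) of NAA50 and the 5 tested genes on each side, above their positions on chromosome 5 in kb, with the exons of NAA50 and AT5G11350 in black and the other genes as grey bars. NAA50 at 6.67 and AT5G11350 at 5.13 stand apart from the other neighbours.

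The comparison of the genotypes asked which transcripts differ in buds of the mutant. Of 21196 genes tested, 2021 passed an adjusted p of 0.05 in edgeR, of which 836 were higher and 1185 lower in the libraries labelled naa50-1. A change of at least 2-fold was seen in 570 of the higher and 1002 of the lower genes. Ranked by fitted log2 fold change, the first 7 falls were in CWINV2, a cell wall invertase, SPH23, an S-protein homolog, PME28, a putative pectinesterase, LCR11, a defensin-like protein, and AT3G28810, AT3G20220 and AT1G51250. None of these 7 genes had a count in the 3 libraries labelled naa50-1, so that their fitted values depend on a prior count and their folds are bounds, which do not show them to be the largest falls. Against a floor of 3 counts over those libraries, CWINV2 was at least 400.3-fold lower (19.4 ± 6.97 CPM in the wild type), SPH23 at least 376-fold, PME28 at least 339-fold and AT1G51250 at least 211-fold. AT3G28810 has a near-identical transcript in AT3G28820, which also fell (log2 fold change -7.34), and AT3G20220 overlaps AT3G20230, so the values of both are uncertain. The first rises by the same ranking, besides NAA50, were in CML47, a probable calcium-binding protein, MSRB8, CRK23, a putative receptor-like kinase, BGLU31, a beta-glucosidase, and the adjacent genes AT5G22520 and AT5G22530. Each of these had 1 to 3 counts over the wild-type libraries, so that their ratios are wide. CML47 reached 7.89 ± 3.80 CPM, a ratio of 237 with a counting interval of 65.8 to 1979, and BGLU31 5.85 ± 2.90 CPM, a ratio of 115 with an interval of 40.1 to 575. Single libraries weigh on these values: the wild-type counts of CML47 came from replicate 1 alone, and its fitted log2 fold change of 7.65 became 10.33 without that library, and those of MSRB8 and AT5G22530 moved from 7.46 to 9.35 and from 6.98 to 8.87. Without wild type replicate 3 the values of CRK23, AT5G22520 and BGLU31 moved from 6.93 to 8.83, from 6.75 to 8.65 and from 6.71 to 7.57, and without naa50-1 replicate 2 that of AT5G22530 moved to 6.22. Without the wild-type replicate concerned, CML47, MSRB8, AT5G22530, CRK23 and AT5G22520 had 0 wild-type counts. Their fitted values there depend on a prior count. CRK23 missed the threshold with limma on unfiltered log2(FPKM + 1) (adjusted p from 7.31e-07 to 0.055 over 15 settings).

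Transcripts of mature pollen and the pollen tube fell steeply in the libraries labelled naa50-1. Of 45 tested genes of this list, 40 fell and none rose, and 43 fell when adjusted over the list alone. All 45 had a negative fold change, with a median log2 value of -5.73. PPME1, a pectin methylesterase of pollen, fell from 209 ± 26.8 to 0.651 ± 0.131 CPM, VGD1, another, from 394 ± 83.1 to 2.12 ± 0.926, AHA6, a plasma membrane proton pump, from 121 ± 5.10 to 0.83 ± 0.563, and STP9, a sugar transporter, from 82.2 ± 23.9 to 1.47 ± 0.0777. The log2 fold change of AHA6 was -7.18, or -7.87 without naa50-1 replicate 3. PPME1 has a near-identical transcript in PME48, which fell too (log2 fold change -7.86), so their reads may be divided between them. The list took 0.199% ± 0.0484 of all counts in the wild type and 0.0117% ± 0.00092 in the libraries labelled naa50-1. In the sperm cell list, 3 of 5 tested genes fell and none rose (4 fell when adjusted over the list alone). HTR10, a histone H3 of sperm, was at least 108-fold lower, GEX3 at least 17.8-fold and DAZ2 at least 13.0-fold, all with 0 counts in the libraries labelled naa50-1. The median of this list was -6.70, or -3.70 with the genes at 0 set at their bound; the fitted median moved to -4.36 without naa50-1 replicate 2 and to -4.38 without naa50-1 replicate 3, and 3 to 5 members were called with 1 library left out. The count filter was rerun in each fit with 1 library left out, so the members tested could change with it. Both lists passed camera with a preset correlation of 0.01 (adjusted p = 4.27e-46 and 7.38e-06) and fry (0.000311 and 9.22e-05). With an estimated correlation neither did (adjusted p = 0.165 for each).

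**Figure D2:**
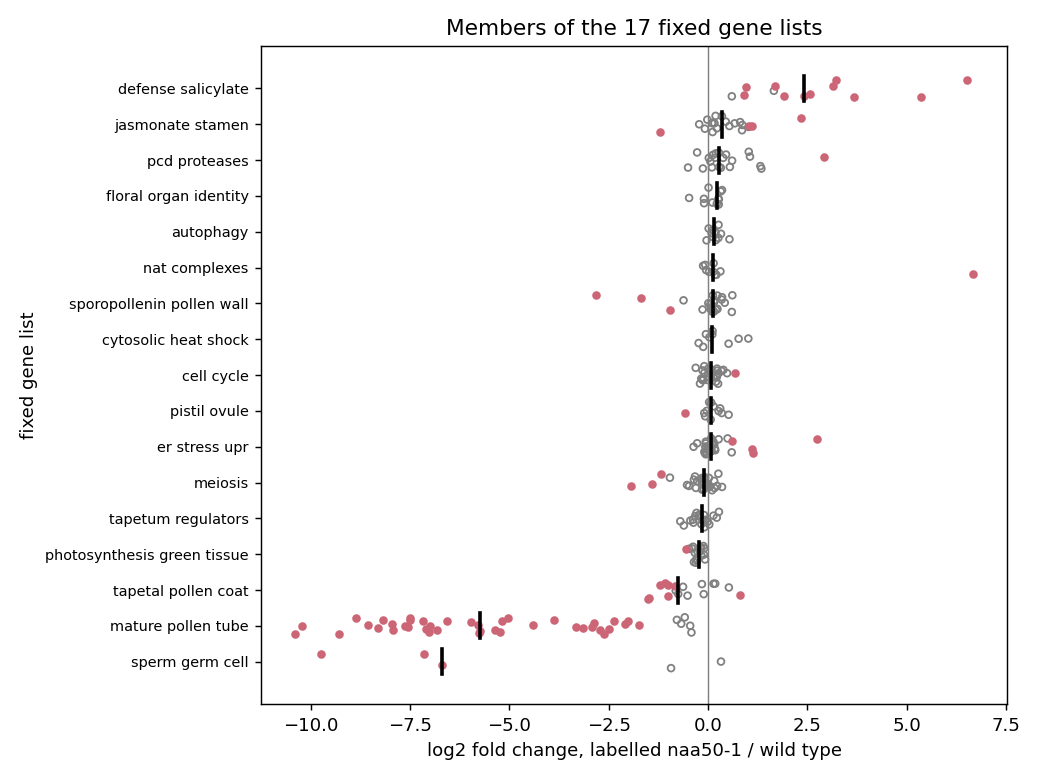
Log2 fold change of each tested member of the 17 fixed gene lists (horizontal axis; libraries labelled naa50-1 against wild type), with filled points past an adjusted p of 0.05 in edgeR, open points not past it, and black bars at the list medians. The mature pollen list has its median at -5.73 and the salicylate defence list at 2.41.

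Among genes of the tapetum, none of 20 tested regulators of tapetum development passed the threshold, over all genes or adjusted over the list alone; 16 had a negative fold change, and the smallest p was that of bHLH089 (log2 fold change -0.61, adjusted p = 0.0614, edgeR). In 3 of 18 alternative settings, DESeq2 among them, bHLH089 was called lower (adjusted p from 0.0274 to 0.211 over the settings), and the list itself passed camera in 1 of 16 (adjusted p from 0.0436 to 0.342), without wild type replicate 3. Of 24 genes of sporopollenin synthesis and the pollen wall, 3 fell and none rose, with the same 3 when adjusted over the list alone; without wild type replicate 1, 3 members were called higher, and 1 without naa50-1 replicate 2. The 3 that fell were CALS5, a callose synthase, from 48.2 ± 10.2 to 6.84 ± 1.74 CPM, SWEET8, a sugar transporter, from 32.1 ± 3.24 to 9.99 ± 0.847, and QRT3, a polygalacturonase that frees microspores, from 95.1 ± 25.2 to 49.0 ± 7.05. QRT3 missed the threshold with limma on unfiltered log2(FPKM + 1) (adjusted p from 5.7e-05 to 0.0547 over 18 settings). The median of that list was 0.11 and its mean -0.09; camera gave it an upward direction and fry a downward one, and neither passed (adjusted p = 0.57 and 0.553); without wild type replicate 1 camera called it upward (adjusted p from 0.0337 to 0.969 over 16 settings). Of 17 pollen coat genes made in the tapetum, 7 fell and 1 rose, or 11 and 1 adjusted over the list alone. All of the 7 falls but 1 were in GRP genes of one cluster on chromosome 5 (AT5G07510 to AT5G07560), as are the genes named next. GRP20, a glycine-rich oleosin-like coat protein, fell from 432 ± 140 to 153 ± 29.3 CPM, GRP16 from 134 ± 54.9 to 47.0 ± 10.3, GRP19 from 720.4 ± 219.9 to 313 ± 63.9, and GRP14 from 205 ± 73.4 to 95.7 ± 19.1. The riser, EXL2, was named after its value was seen (log2 fold change 0.81), and no member was called higher when any 1 library was left out. The coat list passed camera (adjusted p = 0.0153; 0.609 with an estimated correlation and 0.289 by fry), but not without naa50-1 replicate 1 (adjusted p = 0.0549), where 3 members were called lower; over 16 settings the adjusted p ran from 0.000807 to 0.0549. GRP14 lost its call without that library as well (adjusted p from 3.25e-05 to 0.0607 over 18 settings). GRP14 and GRP19 missed the threshold with limma on unfiltered log2(FPKM + 1) too (adjusted p of GRP19 from 6.84e-07 to 0.0527 over 18 settings). Among 21 proteases and other genes of programmed cell death, 1 rose and none fell, in both adjustments; 2 rose without wild type replicate 3 or with scaling by library totals, and 1 rose and 1 fell without wild type replicate 2. The riser was CEP1, a cysteine protease of the tapetum, from 2.07 ± 1.16 to 15.6 ± 9.83 CPM (log2 fold change 2.92, adjusted p = 0.0083, edgeR). With limma-voom CEP1 missed the threshold (adjusted p from 0.00015 to 0.0626 over 18 settings). The list passed camera upward (adjusted p = 0.0153; 0.609 with an estimated correlation and 0.386 by fry). That call was lost without wild type replicate 2 (adjusted p = 0.335) and without naa50-1 replicate 1 (0.054), and the lowest of 16 settings was 0.000675.

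Genes of salicylate-linked defence rose in the libraries labelled naa50-1. Of 13 tested, 11 rose and none fell, with 12 when adjusted over the list alone, and the median log2 fold change was 2.41, or 1.75 without naa50-1 replicate 2. PR2, a glucanase, rose from 2.19 ± 1.04 to 200.04 ± 69.4 CPM, 91.2-fold, and EDS1, a regulator of immune signalling, from 28.3 ± 1.65 to 90.3 ± 16.4. The 2 members not called over all genes were CYP71A13 and NIMIN1 (adjusted p = 0.11 and 0.438, edgeR). PR1, looked up after the values were seen, was called at low and uneven levels (0.533 ± 0.276 to 4.72 ± 4.67 CPM, adjusted p = 0.0325, edgeR). The list passed camera (adjusted p = 1.99e-11; 0.353 with an estimated correlation) and fry (adjusted p = 0.00938). Of 21 genes of jasmonate synthesis and response, 3 rose and 1 fell, or 8 and 1 adjusted over the list alone; with scaling by library totals 7 rose and 1 fell. AOC3, an allene oxide cyclase, rose from 6.11 ± 1.05 to 30.8 ± 9.18 CPM, and MYB24, a stamen regulator, fell from 12.7 ± 2.996 to 5.42 ± 0.945; MYB24 overlaps AT5G40348. The list passed camera upward (adjusted p = 0.00247; 0.609 with an estimated correlation and 0.232 by fry), but not without wild type replicate 2 (adjusted p from 0.00044 to 0.0689 over 16 settings). Of 31 genes of the endoplasmic reticulum stress response, 4 rose and none fell, or 5 adjusted over the list alone. BIP3, an inducible chaperone, rose from 1.202 ± 0.284 to 8.01 ± 2.26 CPM and CRT3, a calreticulin, from 47.0 ± 5.99 to 103 ± 24.2. Camera put the list just past the threshold (adjusted p = 0.0482; 0.609 with an estimated correlation and 0.289 by fry), and the call was lost without wild type replicate 2 (0.437) or naa50-1 replicate 2 (0.188), and in 12 of 16 settings it held (lowest adjusted p 0.017).

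**Figure D3:**
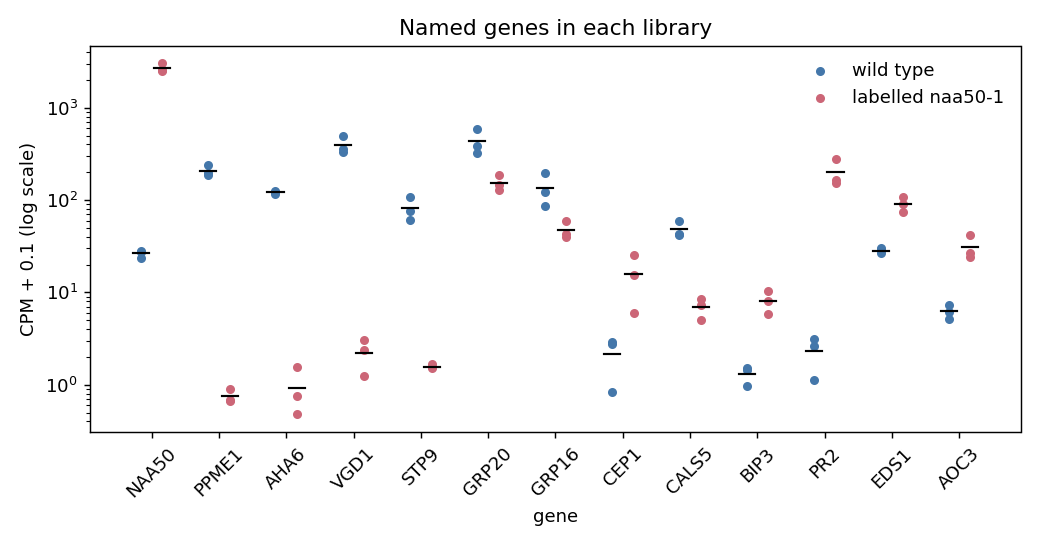
CPM plus 0.1 on a log scale of 13 named genes in each library (points: wild type in blue, libraries labelled naa50-1 in red; black bars: group means). PPME1, VGD1, AHA6 and STP9 lie far lower, and NAA50, PR2 and CEP1 higher, in the libraries labelled naa50-1.

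Markers of other tissues and stages in the buds were examined as well. Of 30 meiosis genes, 3 fell and none rose, in both adjustments: HEI10 (log2 fold change -1.41), SYN1 (-1.93) and ASY1 (-1.18). HEI10 and ASY1 share sequence with overlapping genes. The call of ASY1 (adjusted p = 0.0365, edgeR) was lost when wild type replicate 1 or 3 or any library labelled naa50-1 was left out (adjusted p = 0.106 to 0.126; lowest of 16 settings 0.0323), and with limma-voom (0.0529). The list did not pass camera (adjusted p = 0.0788), but did without wild type replicate 3 or naa50-1 replicate 2 (adjusted p from 0.00764 to 0.277 over 16 settings). All 20 photosynthesis genes had a negative fold change with a median of -0.24, or -0.139 without wild type replicate 1 and -0.14 without naa50-1 replicate 2, but only LHCB6 passed (log2 fold change -0.57), in both adjustments and in 13 of 18 settings (adjusted p from 2.3e-06 to 0.11); the list passed camera (adjusted p = 0.00219; 0.609 with an estimated correlation and 0.232 by fry). Of 12 pistil and ovule genes only CRC fell (log2 fold change -0.59), in both adjustments. None of 11 floral organ identity genes passed in either adjustment (smallest p: SEP2, log2 fold change 0.35, adjusted p = 0.078, edgeR; 0.00824 to 0.22 over 18 settings, 2 of them past the threshold), and none of 12 autophagy genes did (ATG8C, 0.26, adjusted p = 0.216, edgeR). The autophagy list did not pass camera (adjusted p = 0.0788), but did upward without wild type replicate 3 (0.0112) and without naa50-1 replicate 2 (0.036; highest of 16 settings 0.277). Of 27 cell cycle genes CYCB2-1 rose (0.67; past the threshold in 11 of 18 settings, adjusted p from 0.00988 to 0.117), and none adjusted over the list alone. The cell cycle list did not pass camera (adjusted p = 0.0929), but did upward without wild type replicate 1 (0.035) and without naa50-1 replicate 3 (0.0234; highest of 16 settings 0.557). None of 9 cytosolic heat shock genes passed over all genes and 3 rose adjusted over the list alone (HSFB2A, 0.51, adjusted p = 0.0753, edgeR, and 0.0496 with DESeq2 to 0.236 over 18 settings). Without naa50-1 replicate 2, 1 member was called higher over all genes. The heat shock list passed fry (adjusted p = 0.0371) and not camera (0.175). Of 10 subunits of amino-terminal acetylation complexes, NAA50 alone passed, in both adjustments. Camera called the list, in 10 of 16 other settings too (adjusted p = 0.0461, or 0.396 with an estimated correlation), and fry did as well (adjusted p = 0.000311). These set tests were run with NAA50 itself in the list. The other members had log2 fold changes from -0.13 (NAA10) to 0.31 (NAA30), so the list calls are no evidence beyond the rise of NAA50.

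In the authors' deposited table, 2475 genes passed an adjusted p of 0.05, with 1062 higher and 1413 lower. Of these, 1994 were also called by edgeR, all in the same direction.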

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

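The median of the mature pollen list with genes at 0 set at their bound was chosen after the data were seen and stayed at -5.73. Only 1 of the 45 tested members was at its bound, so this median could hardly move. The count of 2021 genes ranged from 1612 (limma on log2(FPKM + 0.1)) to 2395 (DESeq2) over the other scalings, filters, units and tools, and from 1645 to 1926 when 1 library was left out. In those 6 fits, between 1550 and 1657 of the 2021 genes were called in the same direction and 0 reversed. At an adjusted p under 0.01 the count was 1336, with 453 higher, as a stricter threshold must give fewer. NAA50 kept its direction and call under every alternative run, at log2 fold changes of 6.58 to 6.74. The highest correlation between libraries of different labels moved from 0.914 to 0.946 on log2(FPKM + 1); the cause was not tested. The fixed lists were most dependent on the test: 9 passed with the preset correlation, 0 with an estimated correlation and 5 with fry. When 1 library was left out 5 to 11 passed, 5 without wild type replicate 2. The correlations estimated between members ran from -0.0785 (heat shock) to 0.742 (photosynthesis), with 0.35 for mature pollen and 0.615 for salicylate defence. The preset value of 0.01 lies far below those of the pollen, defence and photosynthesis lists, so their preset p-values take members as nearly independent. Of the keyword families 7 passed, 9 with fry and 0 with an estimated correlation, and the correlations within families were not examined. Directions of the set test turned for sets that passed in neither of the settings compared: the expansin family (median 0.0781, 0.10 and 0.0121 in the FPKM settings, 0.133 without wild type replicate 3; -0.00628 to 0.133 with 1 library left out), the sporopollenin list (0.01002 without wild type replicate 2; 0.01002 to 0.263 with 1 library left out; 0.113 with fry), the ribosomal protein family (0.00108 without wild type replicate 2; -0.0813 to 0.00108 with 1 library left out) and the GDSL lipase family (0.027 without wild type replicate 2; 0.027 to 0.212 with 1 library left out; 0.15 with fry). The cause was not tested. Over single named genes, lists and families, 1240 values kept direction and side of the threshold, 68 lost the call, 20 gained it and 9 turned direction. The replicate numbers did not pair the libraries (correlations of same-numbered deviations -0.00021, 0.0585 and 0.102); with the replicate block 1969 genes were called, ASY1 (adjusted p = 0.0783), CYCB2-1 (0.0504), the ER stress and acetylation complex lists (0.0634 each) and the polygalacturonase family (0.0968) were not, bHLH089 (0.0414) and the autophagy list (0.0408) were, and 4 cell death genes were called higher in place of 1. In simulated counts at this depth and number of libraries, 17.9% of genes changed by 1.5-fold were recovered, and what limits this was not tested. The simulation changed far fewer genes than were called in the data and none with low counts, so this rate need not hold for the data.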

Other observations

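Gene families matched by description before the data were examined were tested as well. They can share members with the lists, as PPME1 and VGD1 of the mature pollen list are pectinesterases by description. Defensin-like genes fell most by median: of 36 tested, 26 fell and none rose, with a median log2 fold change of -6.16 (camera adjusted p = 4.14e-26; adjusted p = 0.0613 with an estimated correlation). The file holds 257 such genes, and the rest were removed by the count filter. No median with genes at 0 set at their bound was computed for families, and fitted values of such genes depend on a prior count. Of 26 plant invertase inhibitors 14 fell and none rose, of 77 pectinesterases 30 fell and 3 rose, and of 41 polygalacturonases 9 fell and none rose (camera adjusted p = 2.65e-07, 9.31e-07 and 0.00842, and with an estimated correlation 0.0613, 0.142 and 0.142). Their median log2 fold changes were -2.11, -0.25 and -0.06, so the falls of pectinesterases and polygalacturonases lay in a part of their members. Among 47 WRKY transcription factors 14 rose and 3 fell, and among 49 peroxidases 10 rose and 3 fell (camera adjusted p = 1.64e-07 and 0.00553; adjusted p = 0.17 and 0.188 with an estimated correlation). Of 109 cytochrome P450 genes 12 rose and 6 fell (camera adjusted p = 0.00694; adjusted p = 0.423 with an estimated correlation). The P450 call was lost without wild type replicate 2 (0.219), without naa50-1 replicate 1 (0.135), on unfiltered FPKM (0.0714) and with fry (0.0714). Over 16 settings its adjusted p started at 0.00447. The peroxidase call was lost in 3 of 16 settings (adjusted p from 0.0002 to 0.127). The families of ribosomal proteins, pectate lyases, expansins, lipid transfer proteins, glycine-rich proteins and GDSL lipases did not pass camera. Of these, fry called pectate lyases, expansins and lipid transfer proteins lower (adjusted p = 0.0126, 0.0439 and 0.0229), and camera called pectate lyases lower without wild type replicate 2 (0.0204; highest of 16 settings 0.292). By fry 9 of the 13 families passed.

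Protein domains given in the deposited files were tested by Fisher's exact test over 8128 tested genes with a domain, a test added after the data were seen. Of 404 tests 11 passed. Genes with a TIR domain, found in many immune receptors, were called higher in 29 of 76 cases, where 3.83 were expected (adjusted p = 3.42e-16), and WRKY domain genes in 15 of 51 (adjusted p = 1.31e-06). Self-incompatibility S1 domain genes were called lower in 11 of 12 cases (adjusted p = 2.34e-11) and sodium/proton exchangers in 13 of 32 (adjusted p = 3.82e-07). Of 286 genes with the domain Pkinase_Tyr, 36 were called higher and 31 lower, and both directions passed. Fisher's test takes genes as independent, though all were measured in the same 6 libraries. Its p-values therefore do not measure the spread between libraries.

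The tests of the NAA50 and defence patterns below, and that of scaling for pollen, were chosen after the results were seen. Only the splits of the samples and the bounds for younger buds were written before. With 10 splits of the 6 libraries into 3 and 3, no share under 0.05 can be reached; 1 split, the real one, gave 2021 genes and the highest other gave 0.

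NAA50 and AT5G11350 rose together in the libraries labelled naa50-1. An exchange of the genotype labels would put the pollen transcripts of a fertile wild type in those libraries, if its buds held mature pollen. The mature pollen list had a median of -5.73 there. Since younger buds cannot be told apart from genotype (below), this value does not exclude an exchange. Transcription running from the NAA50 locus into the neighbour on the same strand stays open: 1 of the 10 tested neighbours, AT5G11350, rose by at least 2 on the log2 scale, but that rise is part of the pattern and does not favour this over another cause. Counting reads of the shared 58 bases for both genes stays open too, since AT5G11350 gained 0.35 times the reads NAA50 gained, against a share of shared bases of 0.0573, and the fragment length is not given in the sources used here. Whether the transcripts encode the full protein was not tested.

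The fall of mature pollen transcripts did not come from scaling, since the list median was -5.71 or lower under the 4 other scalings. Younger buds in the libraries labelled naa50-1 would lower late flower genes outside the pollen to a median of -1 or below and raise meiosis genes, and a late median above -0.5, or no rise of meiosis genes, was set as evidence against this before the values were seen. The 9 late genes had a median of -0.23, with an order-statistic interval across genes (coverage 96.1%) of -1.59 to 0.18 that includes -1 and does not decide, while the 30 meiosis genes had a median of -0.11 with such an interval (coverage 95.7%) of -0.28 to -0.02 (median -0.03 without wild type replicate 2 and -0.21 without naa50-1 replicate 2), but its members go both ways (9 above 0 and 21 below) and the prediction gave no size of rise, so that it decides nothing and younger buds cannot be told apart from an effect of genotype. That bound came with no measure of spread: a two-sided exact sign-flip test of the late genes against -1 was tried first (p = 0.0938, n = 9) and the intervals were added after its value was seen; the medians themselves meet the bound set against younger buds, and how to weigh their spread was settled only with the values known. The intervals and the sign-flip test treat genes measured in the same libraries as independent, so they do not measure the spread between libraries. CWINV4, TPS24 and MYB24 among the late genes fell, and an effect of the genotype stays open, untested.

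The rise of salicylate defence genes did not rest on a single library, since at least 9 members were called without any 1 library (with a median of 1.75 without naa50-1 replicate 2), nor on scaling, since the median was 2.41 or higher under the 4 other scalings. Infection or growth conditions shared by the plants of one label cannot be told apart from genotype: the median of 2.41 would be the same, and no label gives how the plants were grown. An effect of the genotype stays open, untested.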
